A study of Oryza sativa Indica Group with 8 samples.

How the data were processed

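The labels describe 8 small RNA libraries from rice panicles, made with a TruSeq small RNA kit from total RNA and sequenced on an Illumina instrument. They cover 4 genotypes (Basmati370, KolaJoha, ThururBhog and IC463254) at 2 nitrogen levels, labelled low and rec, with 1 library per genotype and nitrogen level. The labels give the organism as the Indica group, and the series' design text names a japonica reference. According to that text, the authors trimmed adapters, removed other non-coding RNA, quantified known miRNAs and searched for new ones. The submitters' processing notes name fastp, Bowtie, bedtools and Subread; their versions and the genome build are not given in the sources used here.

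The authors deposited an annotation of known miRNAs, a table whose rows are known miRNAs, and a table whose rows are loci that the authors list as new miRNA loci, called predicted loci here. The 2 tables hold 16 per-library columns under names that match no title, description or other label of the 8 samples. Those columns could not be given to a genotype or a nitrogen level, and the order of columns is no evidence of which sample they belong to. They were seen when the files were first inspected, and none of their values was used. The planned tests of low against rec nitrogen and of the genotypes, and the tests of miRNA families fixed before the data were examined, were therefore not run. The rule for named miRNAs, which chose them by those tests, could not be applied either. Identifiers and loci named in the text were chosen after the lists had been seen. The depth of each library is not given here, for the same reason.

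What was analysed is the part of the files that belongs to no single sample. For known miRNAs it is the RNAcentral identifier of each row and the position of every alignment in the annotation, counted from 1 as in GFF files. For predicted loci it is the chromosome, start and end in the row name. The row names carry no strand and do not say from where the start is counted, so a length is given as end minus start and could be short by 1 base. The files do not pair the identifiers with miRNA names, and the gene table used here, made on the assembly ASM3414082v1, held no miRNA genes, so identifiers are printed as deposited. Positions are those of the authors' unnamed build, and none was compared with the gene table. It was assumed that the annotation and the predicted loci share a build, since they come from the same study and use the same chromosome names.

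The length of a known miRNA is the sum of its aligned exons. Of the 1233 alignments, 5 had a gap. Overlaps needed at least 1 base and were taken on the same strand between known miRNAs and on either strand with predicted loci. Shares of identifiers with more than 1 locus were compared between 21-, 22- and 24-nt miRNAs with 2-sided Fisher's exact tests, and mean numbers of loci with 2-sided permutation tests (100000 resamples), both with Benjamini-Hochberg adjustment over 3 comparisons. Shares of the 12 chromosomes were compared with a permutation test of the chi-square statistic (100000 resamples). Neighbours were consecutive loci at most 10 kb apart. Their number was compared with 10000 random placements of the loci along each chromosome, between the outermost listed positions, as a 1-sided permutation test. Intervals on shares are exact 95% Clopper-Pearson intervals. Loci and identifiers are related by duplication and are not independent replicates, so the p-values describe these lists and carry no replicate error of an experiment.

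The code of the placement test was run on simulated data. Of 40 sets of 1011 unclustered loci, 0 gave a permutation p under 0.05. A further 60 planted neighbours raised the count by 60.3 on average. That rise concerns the counting of neighbours alone. No permutation p was taken for the planted sets, so whether the test detects clustering was not tested. The simulated loci were drawn uniformly, as in the test itself, with fewer placements per set than for the real loci. The check therefore could not show how the test behaves where the density of loci is uneven. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used. All alternatives reported in the closing section were chosen after seeing the files.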

Results

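The study sequenced small RNAs from panicles of 4 rice genotypes at 2 nitrogen levels, in 8 libraries. Its title describes efficient and non-efficient genotypes and the uptake of nitrogen; the labels do not say which genotype belongs to which class. The design implies a comparison of low with rec nitrogen over the genotypes (4 libraries per level), a comparison among the genotypes, and the response to nitrogen within each genotype. None of these comparisons was made, because the columns of the count tables could not be matched to the labelled samples. No expression value, fold change or replicate error is reported. The results below describe the miRNAs and loci over which the authors counted.

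The known set held 285 identifiers, all of which had at least 1 position in the annotation. MicroRNAs are short RNAs cut from hairpin precursors that guide the silencing of matching transcripts. The 21-nt class was the most common, with 159 identifiers (55.8% of the set). There were 52 identifiers of 24 nt, 44 of 22 nt, 23 of 20 nt and 5 of 23 nt. A further 2 identifiers were 99 and 106 nt long, beyond the length of a mature miRNA.

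**Figure D1:**
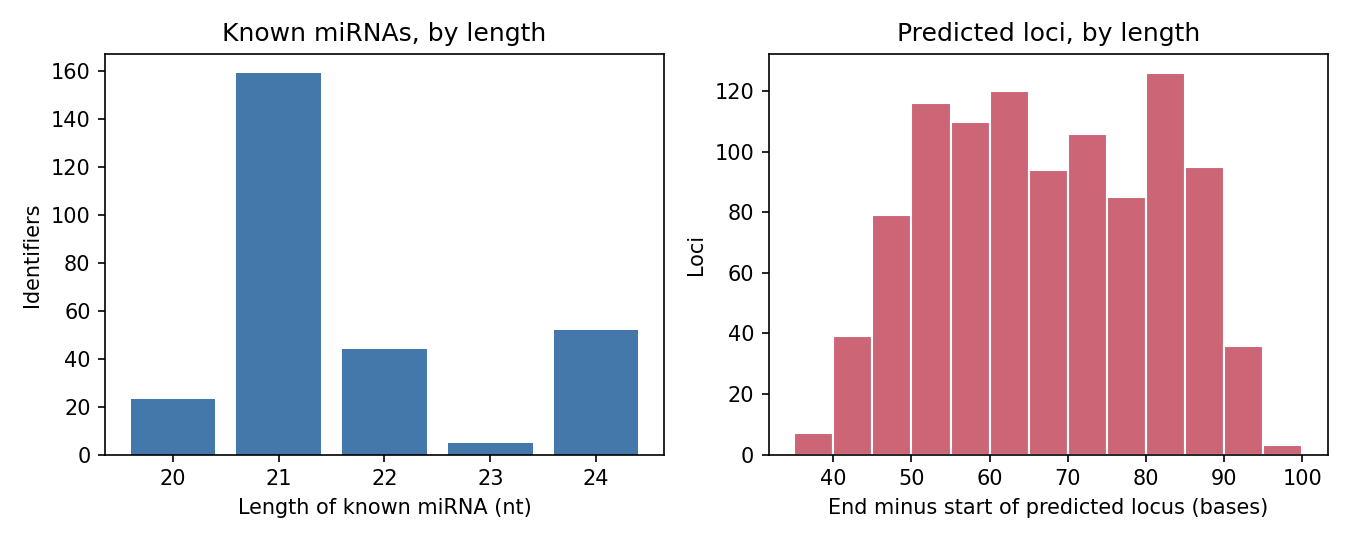
Left, the number of known miRNA identifiers (bars) at each length in nt, without the 2 longer entries of 99 and 106 nt. Right, the number of predicted loci (bars) by end minus start in bases; known miRNAs peak at 21 nt with 159 identifiers, and predicted loci spread from 36 to 99 bases.

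The 285 identifiers aligned to 1233 loci. A single locus was listed for 193 of them, and 92 (32.3%) had more than 1. The spread was wide: the median was 1 locus per identifier and the mean 4.33. The 19 identifiers with 10 or more loci supplied 64.4% of all loci. The 22-nt miRNA URS000038C249 alone had 352 loci (28.5% of the total), and the 21-nt miRNA URS00001E48E8 had 87 (7.06%). Reads of such a miRNA match many places in the genome, and how the authors' counting treated them is not given in the sources used here.

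The share of identifiers with several loci was higher at 22 nt than at 21 nt, by a margin that passed the test with every identifier and locus counted. More than 1 locus was listed for 22 of 44 identifiers of 22 nt (50%, 95% interval 34.6 to 65.4) and for 46 of 159 of 21 nt (28.9%, 22.02 to 36.64). The adjusted p was 0.034 in Fisher's exact test. It was 0.053 without URS000038C249 and 0.086 with loci on chromosomes 1 to 12 alone (Fisher's exact test), which ended the call. Among 24-nt miRNAs the share was 17 of 52 (32.7%, 20.3 to 47.1), which did not pass the test against 21 nt (adjusted p = 0.60, Fisher's exact test) or against 22 nt (adjusted p = 0.15, Fisher's exact test). The mean number of loci was 12.6 ± 52.8 (SD, n = 44) at 22 nt, 2.96 ± 8.23 (SD, n = 159) at 21 nt and 3.08 ± 6.83 (SD, n = 52) at 24 nt. The medians were 1.5, 1.0 and 1.0. URS000038C249 alone gave 352 of the 555 loci at 22 nt, so the mean there rests largely on 1 identifier. None of the 3 differences in the mean passed a permutation test; the smallest adjusted p was 0.17, for 22 against 21 nt.

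A small part of the known loci shared bases with a locus of another identifier on the same strand: 18 of 1233 loci (1.46%), belonging to 14 identifiers. Counting either kind of ambiguity, 98 of the 285 identifiers (34.4%) had more than 1 locus or an overlapping one, and 187 had 1 locus and no overlap. Organelle genomes carried 18 known loci on Mt and 7 on Pt, the names the annotation gives 2 of its sequences. These came from 6 identifiers, each of which also had a locus on chromosomes 1 to 12.

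The predicted loci, which the authors list as miRNA loci outside the known set, numbered 1016, of which 1011 lay on chromosomes 1 to 12, 1 on Mt and 4 on other sequences. Their median length was 66 bases (mean 66.9 ± 14.1, SD, n = 1016), with a range from 36 to 99. No predicted locus overlapped another predicted locus.

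The predicted and known sets were almost separate. Since the predicted list holds loci that the authors listed as new, this can follow from how the list was made. Of the 1016 predicted loci, 2 overlapped a known locus (0.197%, 95% interval 0.0238 to 0.709). On chromosome 11, the predicted locus from 6404197 to 6404279 contained URS000049728D, a 21-nt miRNA with 1 listed locus, at 6404255 to 6404275 on the minus strand. On chromosome 7, the predicted locus from 22061919 to 22062006 contained a gapped alignment of URS0000335BA0, a 24-nt miRNA with 5 listed loci, at 22061925 to 22061959 on the plus strand. Whether these positions fall in genes was not analysed here, since no annotation of the authors' build was used.

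Known and predicted loci were spread over all 12 chromosomes. Chromosome 1 held 111 predicted loci, the most, and chromosome 10 held 41, the fewest. These are counts that were not set against chromosome length. Chromosome 2 held 14.5% of the 193 single-locus known miRNAs and 9.10% of the 1011 predicted loci, while chromosome 9 held 2.07% and 5.93%. Counting every locus of the multi-locus miRNAs gave 1205 known loci on these chromosomes. Such counts rest largely on few miRNAs, since 19 identifiers supplied 64.4% of the known loci on all sequences. The shares of known loci were then 9.88% on chromosome 2 and 5.48% on chromosome 9, closer to those of the predicted loci. This did not hold for every chromosome. Chromosome 11 held 10.9% of single-locus known miRNAs, 7.22% of all known loci and 10.4% of predicted loci. The distributions of single-locus known miRNAs and predicted loci differed in a permutation test (chi-square 23.1, p = 0.016). That test counted each locus as independent, although both sets held close neighbours. With neighbours within 10 kb counted as 1 locus (153 known and 919 predicted), the test no longer passed the threshold (chi-square 16.7, p = 0.12, permutation test). On chromosomes 2 and 9, named after the shares had been seen, the shares moved little. They went to 15.03% and 9.25% on chromosome 2 and to 2.61% and 6.42% on chromosome 9.

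**Figure D2:**
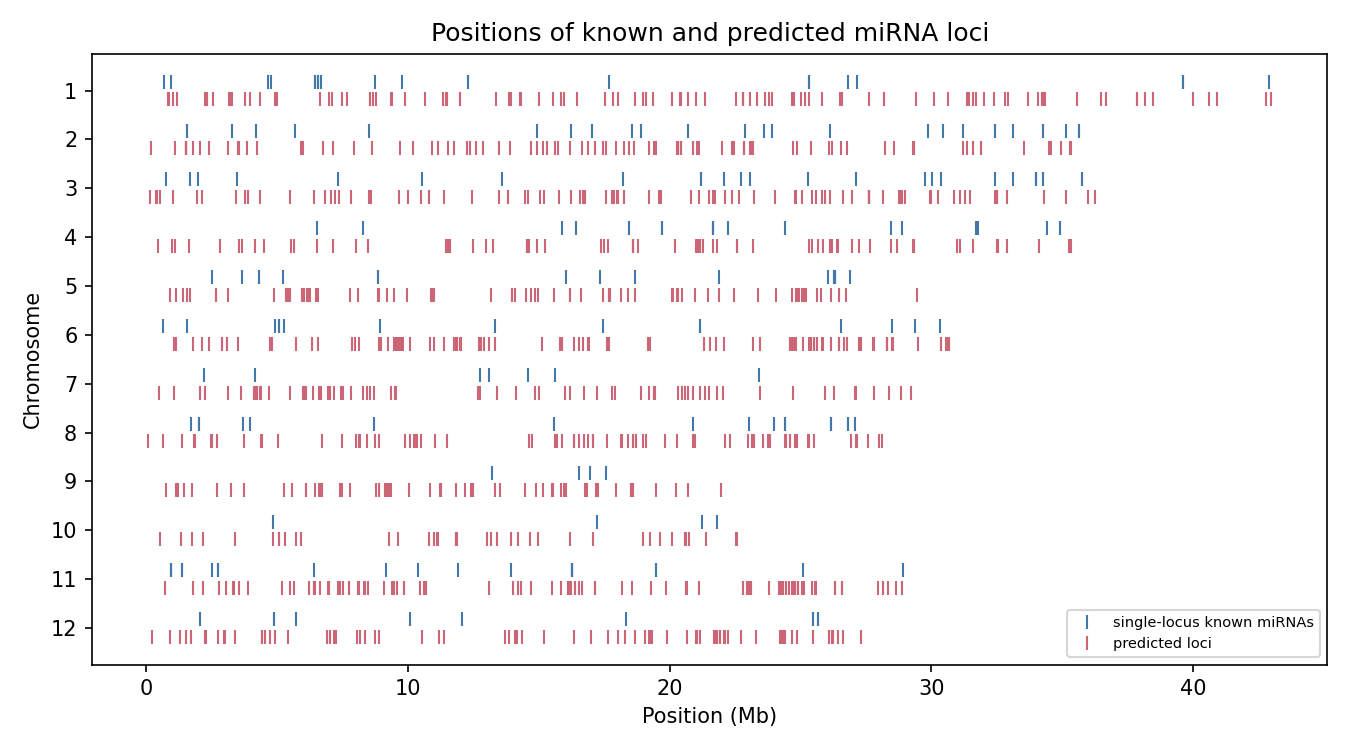
Positions in Mb (x axis) on chromosomes 1 to 12 (y axis) of the 193 known miRNAs with 1 locus (upper, blue ticks) and of the 1011 predicted loci (lower, red ticks), in the authors' coordinates. Chromosome 1 carries the most predicted loci (111) and chromosome 10 the fewest (41), as counts not set against chromosome length.

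Both sets had more close neighbours than uniform random placement gave. For known miRNAs, no placement that keeps an uneven density of loci was tried. Single-locus known miRNAs formed 40 neighbouring pairs within 10 kb, against a mean of 1.10 ± 1.06 (SD) in random placements; the permutation p of 0.0001 is the smallest that 10000 placements can give. In 31 of these pairs, 2 of them overlapping, the members lay within 200 bases of each other, a distance at which both can be arms of one hairpin and then share a strand by construction. The other 9 pairs compared with 1.07 ± 1.05 (SD) in random placements, again with a permutation p of 0.0001. Both members were on the same strand in 9 of these 9 pairs. Among neighbours farther apart they were so in 69 of 141 pairs (48.9%, p = 0.0032, Fisher's exact test). Consecutive pairs can share a member, which the test does not take into account. Arms of one hairpin farther apart than 200 bases were not set aside. Predicted loci formed 92 neighbouring pairs within 10 kb, against 28.1 ± 5.17 (SD) in random placements, again with the smallest permutation p of 0.0001. The predicted neighbours made up 68 runs that held 160 loci (15.8% of those on chromosomes 1 to 12). There were 15 runs of 3 or more loci, and 4 runs had 5 loci each. The runs of 5 lay on chromosome 2 from 1518879 to 1523091, on chromosome 3 from 27624940 to 27640005, on chromosome 11 from 24765850 to 24783726 and on chromosome 12 from 24303780 to 24324601.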

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

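All alternatives here were chosen after seeing the files. None of the alternatives set before the data were examined (other normalizations, filters, DESeq2, models with and without the genotype, libraries left out, counts summed by family) was run, since each needs columns matched to samples. No paired analysis was possible because the columns carry no genotype. The number of known miRNAs with more than 1 locus was 92, and 91 on chromosomes 1 to 12 alone. The 22-nt class had a higher share of such miRNAs than the 21-nt class by 21.1 percentage points, by 19.9 without the identifier with the most loci and by 18.8 on chromosomes 1 to 12 alone. The direction was kept and the call was not: the p adjusted over 3 comparisons was 0.034, 0.053 and 0.086 (Fisher's exact test). Overlaps among known loci went from 18 to 16 when 15 bases were required, and 2 predicted loci lay within 100 bases of a known locus, the same number as overlapped one. The test of chromosome shares no longer passed the threshold when neighbours within 10 kb were counted as 1 locus (chi-square 23.1 before, 16.7 after). This setting leaves fewer loci, and the shares of chromosomes 2 and 9 stayed about as far apart as before. Predicted neighbours numbered 28 within 1 kb and 221 within 50 kb, above 3.0 and 132 in uniform placements. Wider windows hold the narrower ones, so these are not separate tests. Known neighbours within 10 kb fell from 40 to 9 without the pairs within 200 bases, above the uniform random placements both times. Placements that moved each locus were not run for known miRNAs. How many loci the authors listed as new can depend on the depth of their libraries, which was not tested here.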

Other observations

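The test of uneven density was chosen after the number of predicted neighbours had been seen. Predicted loci had 92 neighbours within 10 kb where uniform placement gave 28.1. Placements that moved each locus by up to 500 kb to either side gave 37.1 neighbours on average. The upper end of their central 95% range was 49, below the 92 observed. This argues against uneven density of loci along the chromosomes as the whole cause, on scales broader than the moves. Shorter dense stretches are smoothed away by the moves, so the test cannot decide on them. One precursor listed in pieces is also argued against as the whole cause, since 14 neighbours lay within 200 bases and the excess over that upper end was 43. It may account for part of the excess. Local duplication and other reasons for clustering stay open and were not tested, and no biological explanation was tested because the design names none for positions.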
